A study of Mus musculus with 2 samples.

How the data were processed

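Polyadenylated RNA was sequenced from PDGFRa-positive cells sorted from the stromal vascular fraction (the non-adipocyte cells left after collagenase digestion) of mouse inguinal white adipose tissue. Per the labels, the mice were male, 3 weeks old and given doxycycline at postnatal day 1, RNA was extracted with TriZol-LS, and libraries were made with PrepX on an Apollo 324. There were 2 libraries, 1 from Sox9 floxed mice and 1 from Sox9 PreASKO mice, and the series design text states that 3 mice were pooled for a sample. Mice within a pool cannot be separated, so no spread between animals could be computed.

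The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the gene annotation and the use of strand are not given in the sources used here. The deposited table gives, per the file headers, a raw count per gene and library in whole numbers. It also gives, per the file headers, a repeat-distributed count, treated here as an estimated count because its values need not be whole. The meaning of that name is not stated. Of both counts added together, the raw count held 21.9% in the floxed and 24.4% in the PreASKO library. How reads were divided between these columns is not stated. The authors' deposited table further gives a fold change of PreASKO over floxed, a ratio whose normalization is not stated.

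The main measure was the sum of the raw and the repeat-distributed count of each gene, divided by the library total and expressed as CPM, the usual scaling of counts to library size. This sum was chosen after the columns were compared with the fold change in the authors' deposited table. Among 11991 rows with at least 100 counts in each library, that fold divided by the ratio of summed counts lay within 5% of its median, 1.68, for 97.8% of rows. The share was 14.6% with the raw count alone and 69.4% with the repeat-distributed count alone. The table had 23669 rows, of which 24 carried a date in place of a gene symbol and were resolved by Entrez gene ID. Rows sharing a gene ID were summed for 21 IDs, which left 23647 genes, and 22168 rows matched a gene ID of the RefSeq annotation of the mouse assembly from which coordinates were taken. That assembly is the one mm10 is based on.

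Ratios are log2(CPM + 1) in PreASKO minus log2(CPM + 1) in floxed, which understates differences of low genes, for 13684 genes with a mean of at least 1 CPM. The series design text names a 2-fold cutoff, which was used to count genes by size. With 1 library per genotype there is no replicate check, no test between genotypes and no p-value. Counting intervals are exact 95% Poisson intervals for levels and exact 95% binomial (Clopper-Pearson) intervals for ratios of CPM, with estimated counts rounded to whole numbers. They cover counting error only, and compare these libraries and not the genotypes. The floxed library held 61761645 counts and the PreASKO library 37597048, so the PreASKO values of low genes are the less precise ones.

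Of 36 gene lists, those with at least 5 measured members received a percentile: the rank of the list's median ratio among 10000 random lists of the same size, matched in 20 bins of mean expression. Medians below the 2.5th or above the 97.5th percentile are called outside the central 95%. Percentiles describe these libraries and are not p-values. The genes named are the 12 highest and 12 lowest ratios among genes with a mean of at least 5 CPM, without predicted or unnamed models, pseudogenes and small RNAs, then 4 genes tied to the study's question, genes that check the labelled sex, and up to 4 members with the largest ratios of each list. Members named beyond this rule were chosen after their values were seen. The lists, this rule, the 2-fold cutoff, the filter, the pseudocount and 9 alternatives were set before the data were examined, and 4 alternatives were added afterwards. The written rule took as cell type markers all lists sharing a name prefix that the cell cycle list also carries. That list was moved to the functional lists after the data were seen, which leaves 23 functional and 5 cell type lists with a percentile. The 5 genes that check the labelled sex are not counted among these lists. List members without a matching row were not analysed here.

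The procedure was tested on simulated counts for this comparison, with 200 genes changed in each run. Of genes changed 3-fold, 91.5% passed the 2-fold cutoff (13681 genes in the run), of those changed 4-fold, 96% (13671 genes), and of those changed 1.5-fold, 0%. Unchanged genes past the cutoff numbered 0, although the simulation held counting error alone. For gene lists, independent spread was added to each simulated gene. A list of 20 genes shifted by -0.7 had a recovered median of -0.50. Of 200 unshifted simulated lists, 4% fell outside the central 95% (13694 genes). These lists were random draws, so that share was set by design and does not cover lists of genes regulated together. Intervals for differences between list medians came from 2000 bootstrap draws of list members. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.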

Results

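Gene expression was compared between PDGFRa-positive inguinal adipose stromal cells of Sox9 floxed mice and of Sox9 PreASKO mice, with 1 pooled library each. Sox9 is a transcription factor best known from cartilage, and the study's title places it with Meis1 upstream of the passage from Pref-1-positive to PDGFRa-positive adipose precursors. The floxed library held 61761645 counts over 21976 detected genes and the PreASKO library 37597048 over 20784. Among genes with a row, the 10 most abundant took 5.74% and 6.07% of counts, led by Fn1 in the floxed and Gsn in the PreASKO library. No row matched Col1a1, Col1a2, Col3a1, Sparc or Dcn, so the ranking and the library totals do not cover these matrix genes. No replicate check exists for any difference given here, and intervals cover counting error only.

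Sox9 and Meis1 were both lower in the PreASKO library, and Dlk1, which encodes Pref-1, was far lower. Sox9 (Entrez ID 20682; chromosome 11, 112782210 to 112787757, mm10) stood at 28.6 CPM in floxed (1768 counts) and 17.0 CPM in PreASKO (640 counts), a ratio of 0.595 (95% interval 0.542 to 0.651). Meis1, a homeobox transcription factor (ID 17268; chromosome 11, 18880428 to 19019651), stood at 30.4 and 19.5 CPM, a ratio of 0.642 (0.589 to 0.700). Dlk1 (ID 13386; chromosome 12, 109452485 to 109463336) stood at 105 and 16.2 CPM, a ratio of 0.154 (0.142 to 0.167). Pdgfra, the gene of the sorting marker (ID 18595; chromosome 5, 75151322 to 75198206), stood at 716 and 603 CPM, a ratio of 0.842 (0.829 to 0.856). Counts per gene do not resolve the deleted part of Sox9, so the remaining Sox9 counts do not measure intact transcript. The log2 ratio of Sox9 was -0.72, against -1.17 with the raw count alone, and that of Meis1 was -0.61, against -0.14 with the raw count alone, which holds few of its counts.

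One library did not match its labelled sex. Xist, the noncoding RNA of the inactive X chromosome in females (chromosome X, 103460373 to 103483233), stood at 3.24 CPM in floxed and 745 CPM in PreASKO, although both pools are labelled male. Genes of the Y chromosome were present in both: Ddx3y stood at 40.6 and 39.5 CPM, Eif2s3y at 17.6 and 10.98, Kdm5d at 20.2 and 10.9, and Uty at 12.5 and 9.12. Summed over these genes, the PreASKO library held 70.5 CPM against 90.8 CPM, a ratio of 0.776 (0.741 to 0.813). The library labelled PreASKO therefore carried a female-typical transcript together with male-specific ones, and every difference below compares pools that differ in this as well as in genotype.

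**Figure D1:**
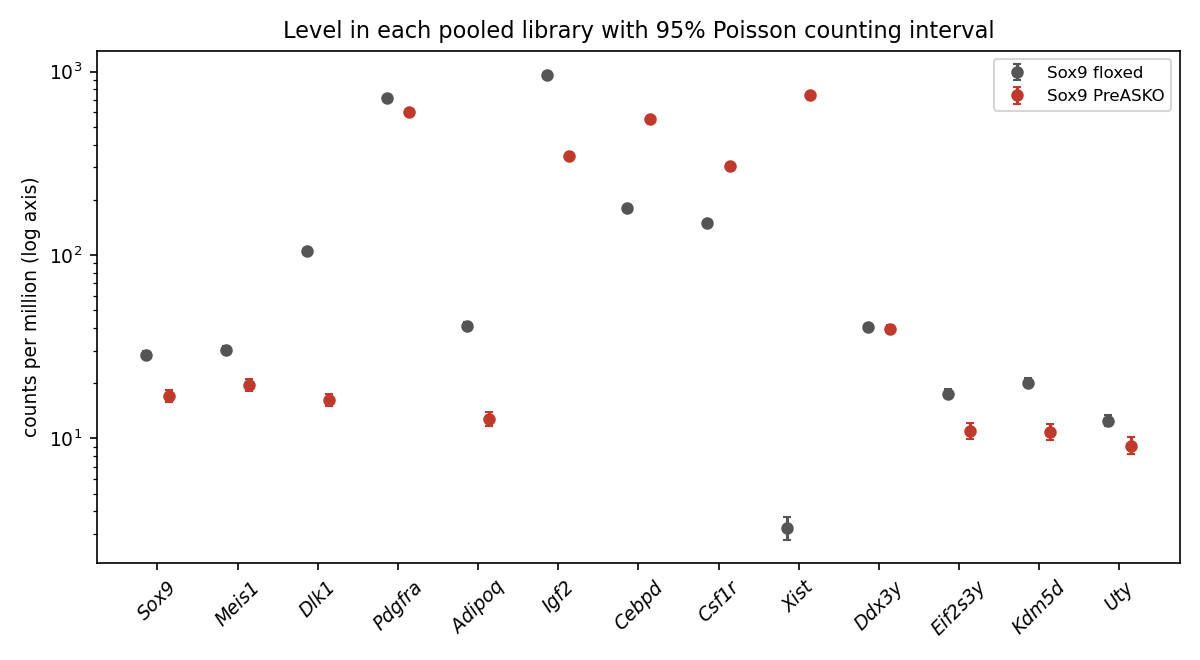
Level of 13 genes in each pooled library, in CPM on a log axis, with points for the floxed (grey) and PreASKO (red) library and bars for the exact 95% Poisson counting interval. Dlk1 lies at 105 CPM in floxed and 16.2 CPM in PreASKO, and Xist at 3.24 and 745 CPM.

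Of 13684 genes, 289 (2.11%) were at least 2-fold higher and 208 (1.52%) at least 2-fold lower in the PreASKO library, while 83.9% lay within 1.5-fold. Behind Xist, the highest ratio belonged to Tnc, the matrix glycoprotein tenascin-C, at 2.38 CPM in floxed and 16.2 CPM in PreASKO (log2 ratio 2.35). The leptin receptor gene Lepr (1.83), the chemokine receptor gene Cxcr4 (1.79), Cebpd (1.62) and the metallothionein gene Mt1 (1.61) were also among the 12 highest. Interferon-response genes made up part of this set, with Rsad2 at 1.92, Ifit3 at 1.77, Oas3 at 1.72 and Gvin1 at 1.62, as did Plbd1 (1.58) and the MHC class II gene H2-Ab1 (1.57). Ifit3 and Gvin1 have near-identical relatives with which reads could be shared, so their values are uncertain. At a pseudocount of 5, Tnc stood at 1.52, and with the repeat-distributed count alone Lepr stood at 0.95 and Rsad2 at 1.10. The lowest value of Oas3 in any alternative was 1.02.

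Among the 12 lowest, Dlk1 led at a log2 ratio of -2.63. Gpd1, an enzyme supplying glycerol phosphate for triglyceride synthesis, stood at 25.1 CPM in floxed and 5.45 CPM in PreASKO (-2.02), and Adipoq, which encodes the adipocyte hormone adiponectin, at 41.2 and 12.8 CPM (-1.61). Igf2, an imprinted fetal growth factor gene, was the most abundant of this set, at 962 and 348 CPM (-1.46, against -2.09 with the raw count alone, which holds 1.15% and 0.773% of its counts). The Wnt ligand gene Wnt2b lay at -1.46. Baiap2l1 (-1.97), Parm1 (-1.64), Rab6b (-1.60) and Slc44a5 (-1.53) were also in this set. Pcdhgc4 (-2.49) and Pcdhga7 (-2.08) share their last exons with the other protocadherin gamma genes, and Rbm3os (-1.63) is antisense with strand use not stated, so these 3 values are uncertain. The number of genes past 2-fold depends on the treatment of low counts, with 58 higher and 28 lower at a pseudocount of 5, and 515 and 412 at 0.1. In the authors' deposited table, 4088 rows had a fold of at least 2 and 4705 a fold of at most 0.5, and 71.1% of these rows had under 20 counts in both libraries.

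**Figure D2:**
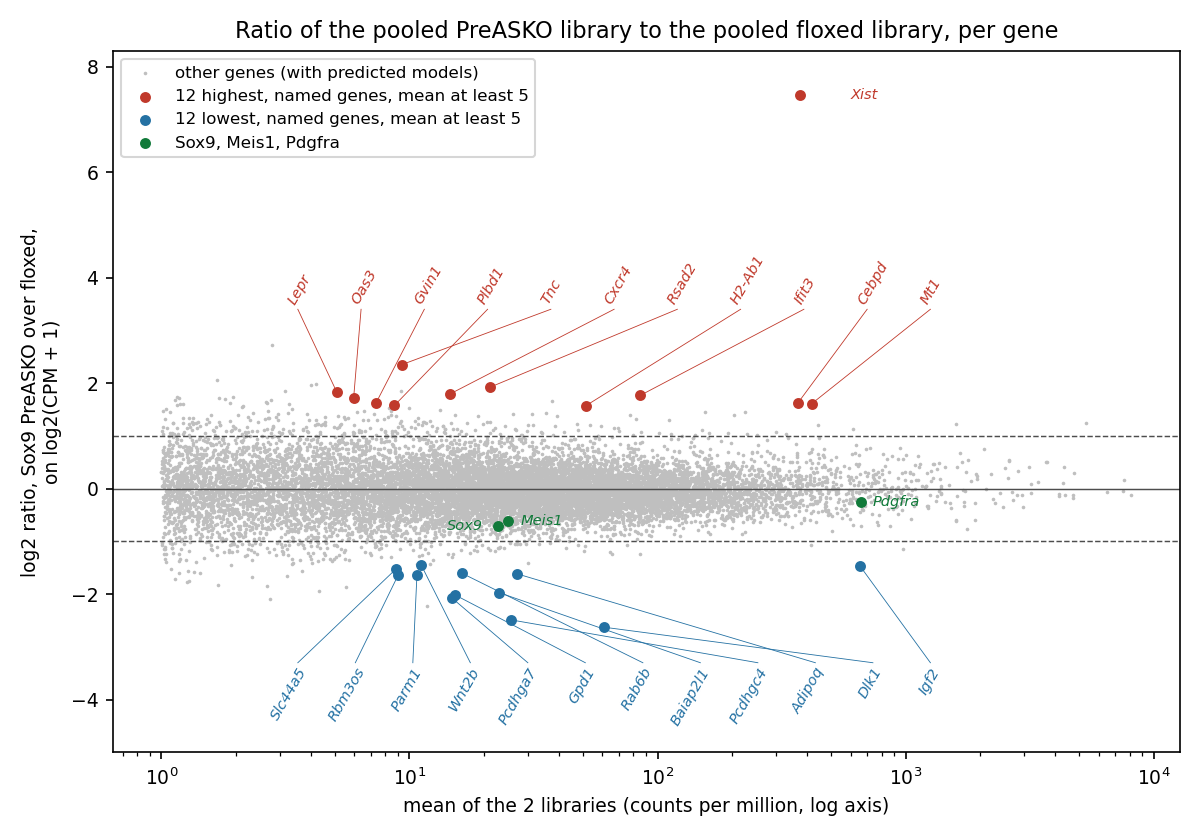
Log2 ratio of PreASKO over floxed against the mean of both libraries in CPM (log axis), one point per gene, with dashed lines at 2-fold. Red and blue points are the 12 highest and 12 lowest named genes with a mean of at least 5 CPM, green points are Sox9, Meis1 and Pdgfra, and grey points beyond them are predicted models or genes below that mean. Xist stands alone at 7.46 and Dlk1 lies lowest at -2.63.

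Genes of mature adipocytes and of cholesterol synthesis were lower together in the PreASKO library. Of 28 measured genes of mature adipocytes, 27 were lower, with a median log2 ratio of -0.55, below all 10000 matched random lists. Besides Gpd1 and Adipoq, the insulin-responsive glucose transporter gene Slc2a4 stood at 6.59 and 1.94 CPM (log2 ratio -1.37, and -0.74 at a pseudocount of 5) and Nnat at 110 and 55.9 CPM. Of 20 cholesterol synthesis genes, 19 were lower, with a median of -0.72, also below all random lists. Hsd17b7 stood at 37.0 CPM in floxed and 17.4 CPM in PreASKO, Dhcr7 at 45.4 and 21.5, Fdft1 (squalene synthase) at 50.1 and 23.9, and Mvd at 10.6 and 4.95.

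The lists of adipogenesis regulators moved apart. Of 24 measured activators of adipogenesis, 15 were lower, and the median of -0.25 lay at percentile 0.62 of random lists. Pparg, the receptor that drives adipocyte differentiation, stood at 139 CPM in floxed and 84.1 CPM in PreASKO, a ratio of 0.603 (0.579 to 0.629). Other activators went the opposite way: Cebpd stood at 180 and 554 CPM, a ratio of 3.08 (3.01 to 3.15), Cebpb at 18.7 and 52.0 CPM, and Bmp4 at 30.6 and 59.2 CPM. Wisp2, at 6.10 and 13.3 CPM, was counted in this list too, although it is described as an inhibitor of adipogenic commitment. Of 20 inhibitors, 13 were higher, with a median of 0.19 at percentile 99.55. Klf2, a repressor of Pparg, stood at 120 and 330 CPM and Twist2 at 30.4 and 58.7 CPM, whereas the Hedgehog pathway genes Gli1 (20.5 and 8.11 CPM) and Ptch1 (30.1 and 17.7 CPM) were lower. With a pseudocount of 5, a minimum mean of 5 CPM or the raw count alone, the activators lay at percentiles 3.56, 3.64 and 22.7, inside the central 95%, and with length and GC adjustment at percentile 8.63. Macrophage (median 0.82) and endothelial markers (median 0.66), from cells that also express Cebpb, Cebpd and Klf2, were higher in the same library. The log2 ratio of Twist2 was 0.93, against 0.12 with the repeat-distributed count alone, and that of Ptch1 was -0.73, against -1.70 with the raw count alone. For Ptch1 the raw count held only 2.42% of counts in floxed and 0.451% in PreASKO. The inhibitors lay inside with the raw count alone (75.3) and the repeat-distributed count alone (90.2).

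Among precursor states, 15 of 19 genes of committed preadipocytes were higher in the PreASKO library, with a median of 0.25 at percentile 99.8. Fabp4, a fatty acid carrier of adipocytes that macrophages and endothelial cells also make, stood at 216 and 443 CPM, Penk at 58.8 and 86.9 CPM and Cxcl14 at 18.3 and 28.4 CPM, while Pparg belongs to this list too and was lower. Macrophage (median 0.82) and endothelial markers (median 0.66) were higher in the same library, and Apoe, Cd36, Col4a1, Col4a2 and Sparcl1, also higher members of this list, are made by such cells too. With the raw count alone, the list median turned to -0.073 and the log2 ratio of Penk from 0.55 to -0.95. For Penk the raw count held 7.43% of counts in floxed and 2.76% in PreASKO. Genes of DPP4-positive progenitors had a median of -0.08 (percentile 32.01), with Pi16 at 2226 and 1306 CPM and Dact2 at 12.1 and 7.13 CPM lower, and Stmn4 and Bmp7 higher. Genes of F3-positive regulatory stromal cells had a median of 0.10 (percentile 86.8), with Mgp at 94.6 and 184 CPM.

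Notch pathway and cell cycle genes were mostly lower in the PreASKO library. Of 8 Notch genes, 7 were lower, with a median of -0.42 at percentile 0.45. Hey1, a Notch target, stood at 17.0 and 6.73 CPM, Notch1 at 40.3 and 22.9 CPM and Lfng at 6.20 and 3.62 CPM. The log2 ratio of Notch1 was -0.79, against -0.064 with the raw count alone, and the Notch target Hes1, kept in the list of adipogenesis inhibitors, was higher at 34.8 and 51.3 CPM. Of 35 cell cycle genes, 27 were lower, with a median of -0.27 at percentile 0.11, among them the replication genes Cdc6 (8.66 and 2.79 CPM), Rrm2 (48.7 and 25.6 CPM) and Mcm2 (48.8 and 30.9 CPM). The 8 higher members included the proliferation marker gene Mki67, which barely differed (162 and 167 CPM), Cenpf (46.2 and 56.1 CPM) and Nusap1 (42.9 and 49.6 CPM). Proliferation itself was not measured. The Notch list lay inside the central 95% with length and GC adjustment (4.53) and with the raw count alone (8.68), and the cell cycle list with the raw count alone (7.94).

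Wnt targets lay just inside the central 95%, with a median of 0.22 at percentile 97.4. They lay outside it in 2 of 11 alternatives, a pseudocount of 0.1 (98.4) and length and GC adjustment (99.2). They lay further inside with a pseudocount of 5 (92.4) and with the raw count alone (82.9). Axin2, a feedback target of Wnt signalling, stood at 10.7 and 16.4 CPM and Dkk2 at 62.01 and 105 CPM, against Apcdd1 at 40.7 and 22.4 CPM. Medians of TGF-beta and BMP genes (-0.06, percentile 41.1), of Meis, Pbx and Hox genes (-0.08, percentile 36.9) and of fibroblast matrix genes (-0.12, percentile 10.035) lay inside as well. Within the matrix list, Mmp3 stood at 82.1 and 159 CPM and Thbs1 at 238 and 168 CPM. Only 6 genes of the Sox9 and cartilage list were measured, with a median of 0.06 (percentile 65.4). Runx2, a skeletal transcription factor, stood at 3.21 and 7.66 CPM and Sox5 at 9.84 and 7.66 CPM.

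Markers of macrophages and of endothelial cells were higher in the PreASKO library. All 16 macrophage markers were higher, with a median of 0.82 above all random lists: Lyz2 stood at 387 and 843 CPM, Csf1r at 150 and 307 CPM, Cd163 at 42.7 and 96.4 CPM and Ms4a7 at 13.7 and 38.4 CPM. Of 11 endothelial markers, 9 were higher, with a median of 0.66 at percentile 99.99, mostly at low levels, as with Kdr at 5.003 and 11.1 CPM, Cdh5 at 3.63 and 7.42 CPM, and Esam and Erg below 3 CPM in both. The endothelial median depended on the treatment of low counts, at 0.93 with a pseudocount of 0.1 and 0.29 with a pseudocount of 5. Restricted to the 6 genes with a mean of at least 5 CPM it was 0.22, at percentile 93.95, inside the central 95%. Among these 6, the abundant Tek, Eng and Lyve1 barely differed (ratios of 0.959, 0.959 and 1.03), while Kdr (2.22), Cdh5 (2.05) and Plvap (1.35) were higher. Tek stood at 154 CPM and Lyve1 at 239 CPM in floxed, far above Cdh5, and which cells made them was not tested. The members below that mean were all higher: Pecam1 (1.94), Vwf (2.41), Egfl7 (1.74), Erg (4.55) and Esam (6.57). Mural (0.02, percentile 61.3), neutrophil and mast cell (-0.12, percentile 32.3) and muscle markers (0.08, percentile 61.4) lay inside the central 95%. With under 5 measured genes and no percentile, medians were 0.24 for T and NK cells, 0.70 for B and plasma cells, 0.95 for erythroid, -0.37 for Schwann, -0.49 for mesothelial and 0.12 for epithelial markers.

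Interferon-response and inflammatory genes were higher in the library that also held more macrophage marker RNA (median 0.82). Of 22 interferon-response genes, 21 were higher, with a median of 0.66 above all random lists. Ifit1 stood at 31.7 and 75.0 CPM and Oasl2 at 95.3 and 208 CPM. The log2 ratio of Oasl2 was 1.11, against 0.18 with the raw count alone, which holds only 0.900% and 0.538% of its counts. Of 20 inflammatory genes, 15 were higher, with a median of 0.36 above all random lists, including Cxcl13 (10.01 and 27.8 CPM), Ccl8 (9.97 and 22.4 CPM), Il1b (2.17 and 4.55 CPM) and Cxcl1 (701 and 1196 CPM). Immediate early and heat shock genes, which respond within minutes to stress and tissue handling, had 15 of 23 members higher and a median of 0.28 at percentile 99.96. Zfp36, an mRNA-destabilizing protein gene, stood at 3173 and 7478 CPM and Jund at 125 and 261 CPM, but Egr3 was lower at 58.9 and 26.3 CPM. The immediate early list lay inside the central 95% with the repeat-distributed count alone (89.4) and with the raw count alone (96.8).

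Mitochondrially encoded transcripts were higher in the PreASKO library, where they took 2.35% of counts against 1.84%. Of 12 such genes, 11 were higher, with a median of 0.46 above all random lists, as with ND3 (37.7 and 74.0 CPM) and COX2 (530 and 907 CPM). Nuclear respiratory chain genes had a median of 0.11 at percentile 98.7, but their largest ratios pointed down, with Atp5b at 1919 and 1259 CPM and Uqcrq at 107 and 69.0 CPM. This list lay inside the central 95% with length and GC adjustment (83.4), the repeat-distributed count alone (95.3) and the raw count alone (90.1). Fatty acid oxidation (-0.08, percentile 44.1), glycolysis and hypoxia (-0.12, percentile 24.1), thermogenic (-0.18, percentile 21.2) and ribosomal protein genes (-0.05, percentile 46.5) lay inside, although fatty acid oxidation lay outside with the repeat-distributed count alone (median -0.26, percentile 1.85). In all, 12 of 23 functional lists and 2 of 5 cell type lists lay outside the central 95%, where 1.4 of the 28 lists would by chance if genes were independent.

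**Figure D3:**
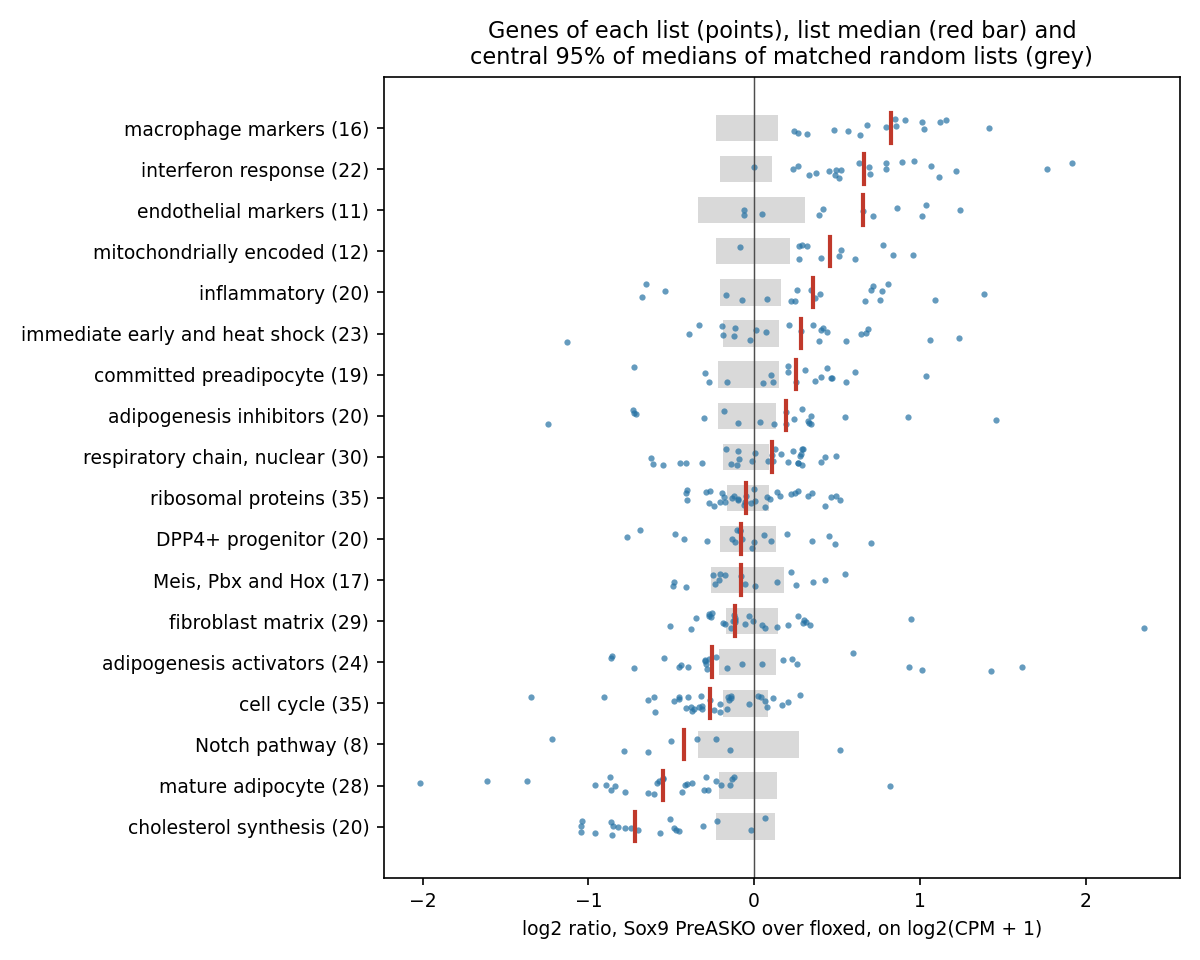
Log2 ratio of PreASKO over floxed for the measured genes of 18 lists (blue points, number of genes in parentheses), with the list median as a red bar and the central 95% of medians of matched random lists in grey. The cholesterol synthesis median lies lowest at -0.72 and the macrophage marker median highest at 0.82.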

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

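The alternatives using the raw count alone, the repeat-distributed count alone, the fold in the authors' deposited table, and length and GC adjustment were tests chosen only after the result was seen. Cholesterol, mature adipocyte, interferon, inflammatory and macrophage lists stayed outside the central 95% in all 11 alternatives run on them, and the mitochondrially encoded list in all 9. Against 289 genes at least 2-fold higher and 208 lower, a pseudocount of 0.1 gave 515 and 412, a pseudocount of 5 gave 58 and 28, a mean of at least 5 CPM gave 153 and 93, a 1.5-fold cutoff 1080 and 1120, and a 3-fold cutoff 30 and 22. The pseudocounts change the ratios of low genes, the cutoffs the ratio required, and the minimum mean the genes admitted, 11038 in place of 13684. The raw count alone gave 465 and 907, and the cause was not tested. Folds in the authors' deposited table, to which no pseudocount was added, gave 597 and 471. Of the main calls they kept 288 higher and 208 lower genes. The smaller pseudocount of 0.1 likewise raised both numbers, and what else contributed was not tested. Of genes past the cutoff, 58.1% were higher in the main analysis, 33.9% with the raw count alone, 49.1% at 1.5-fold and 67.4% with a pseudocount of 5. Dlk1 was -2.38 with a pseudocount of 5. Pdgfra was -0.22 after TMM-style rescaling, -0.57 with the raw count, -0.20 with the repeat-distributed count and -0.18 with length and GC adjustment. For Pdgfra the raw count held 1.09% of counts in floxed and 0.953% in PreASKO. Sox9 was -1.17 with the raw and -0.51 with the repeat-distributed count, and Meis1 -0.14 with the raw count; the cause was not tested. With the raw count alone, 5 functional lists and 1 cell type list, the macrophage markers, lay outside. Of the cell type lists, only the macrophage and mural lists then held at least 5 measured genes, so the endothelial list received no percentile. The committed preadipocyte median reversed to -0.073 with the raw count alone, and the cause was not tested. With a mean of at least 5 CPM, 1 cell type list lay outside. The smaller PreASKO library limits genes of few counts most. Leaving out replicates was not possible with 1 library per genotype. No paired analysis was possible because each genotype has 1 library.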

Other observations

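The tests of a female or mixed pool, of a general rise of other cell types, of dilution, and of fewer adipocyte-like cells were tests chosen only after the result was seen. All gene groups in this part were also put together after the data had been seen. MHC class II genes were higher in the PreASKO library: H2-Eb1 stood at 22.02 CPM in floxed and 46.6 CPM in PreASKO, and H2-Aa at 57.1 and 105 CPM. All 6 measured class II genes other than H2-Ab1 and Cd74 were higher, with a median log2 ratio of 0.89 above all random lists, in the same library as the higher macrophage markers. Glucocorticoid-responsive genes other than Mt1 and Cebpd were also higher, 15 of 18 with a median of 0.52 above all random lists, such as Mt2 (266 and 617 CPM) and Tsc22d3 (38.3 and 77.1 CPM). Fkbp5 (28.8 and 22.3 CPM) and Sgk1 (151 and 142 CPM), typical members of that group, were lower.

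Dlk1 and Igf2 are both imprinted, and H19, the imprinted neighbour of Igf2, stood at 1350 CPM in floxed and 609 CPM in PreASKO. A set of 24 measured imprinted genes, with H19 and without Dlk1, Igf2 and Nnat (110 and 55.9 CPM), which had been seen to be lower, had 18 genes lower and 6 higher. Its median of -0.10 lay at percentile 19.25, inside the central 95%. Of 8 clock output genes, 7 were lower (median -0.52, such as Tef at 29.99 and 16.0 CPM), while Ciart was higher (ratio 3.19). Arntl (0.987), Clock (0.866) and Npas2 (1.40) did not move together against them, with a median log2 ratio of -0.019. The output median minus that of Arntl, Npas2 and Clock was -0.50 (interval -1.10 to -0.14). This difference passed the size of 0.5 set beforehand for pools collected at different clock phases. A requirement on its interval, added after the value was seen, was not met, so a difference in collection time stays open.

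Xist was 230 times as high in the PreASKO library, from pools labelled male. A wholly female pool is excluded, since the lower bound of the summed Y-linked ratio was 0.741. Silencing of the X chromosome in male cells is argued against by the X-linked median, which differed from the autosomal one by 0.0082 (-0.040 to 0.057, 443 X-linked genes). Female beside male cells in the pool may account for Xist, as the Y-linked sum was at 0.776. Against this, a simple mix would lower the Y-linked genes alike, but Ddx3y (0.973, 0.912 to 1.04) and Kdm5d (0.538, 0.480 to 0.603) differed. Female cells would also raise X-linked genes that escape silencing, and 4 such genes had a median log2 ratio of 0.018, with 2 higher and 2 lower. The central range of matched random lists of 4 genes was -0.374 to 0.322. These 4 genes could not show a small rise, so they do not decide on a mix. A difference in sex makeup therefore stays open for other genes too, untested beside the genotype.

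Macrophage markers had a median of 0.82, and a second list of 27 measured macrophage genes, fixed before its values were looked at, had a median of 0.75 with 27 of 27 higher. A larger share of macrophages in the sorted cells may account for this, although the sort for PDGFRa is meant to remove them. Macrophage marker RNA was present in both sorted libraries, with Lyz2 at 387 CPM in floxed and 843 CPM in PreASKO. A rise of all other cell types alike is argued against only for mural, neutrophil and mast cell, and Schwann markers. Their highest median was 0.016, and none of their measured genes exceeded 0.55. These lists were picked after their values were seen, so they do not speak for the rest. Medians of lists left out of this test were -0.49 (mesothelial), 0.08 (muscle), 0.12 (epithelial) and 0.24 (T and NK cells). Endothelial (0.66), B and plasma cell (0.70) and erythroid markers (0.95) were also higher, so a joint rise of several cell types stays open. At a mean of at least 5 CPM the endothelial median was 0.22, where macrophage markers were at 0.82. That smaller endothelial set held Tek, Eng and Lyve1, with ratios of 0.959, 0.959 and 1.03, beside Kdr (2.22), Cdh5 (2.05) and Plvap (1.35). Endothelial markers below that mean were all higher, such as Pecam1 (1.94) and Vwf (2.41). Activation of macrophages already present, and the genotype, stay open.

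Cholesterol synthesis and mature adipocyte genes were lower with medians of -0.72 and -0.55. Length and GC content are argued against as the whole cause, since the adjusted cholesterol median was -0.69, still below the central 95%. Dilution of precursor RNA by other cells would lower fibroblast matrix genes as well. Their median was -0.12, with a difference of -0.60 (-0.87 to -0.36) from the cholesterol list. The 29 matrix genes measured did not include Col1a1, Col1a2, Col3a1, Sparc and Dcn, for which no row matched. Fewer adipocyte-like cells would lower cholesterol genes less than genes restricted to adipocytes. The cholesterol median lay -0.17 from the adipocyte median (-0.42 to 0.11). This comparison cannot decide on that source, because the adipocyte list also held fat synthesis genes that other cells express. Of these, Scd1 had a log2 ratio of -0.42, Acly -0.29 and Fasn -0.86. Gpd1 (-2.02), Adipoq (-1.61) and Slc2a4 (-1.37) fell further, but Plin1 (-0.28) did not. Fewer adipocyte-like cells may still account for the adipocyte genes, although the stromal preparation and the sort would remove adipocytes. Plin4 (ratio 1.83) was also higher, as was Fabp4 (2.05), which macrophages and endothelial cells also make. Genotype, sex makeup and collection time stay open for both groups.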
